A study of Mus musculus with 8 samples.

How the data were processed

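RNA-seq was done on whole mouse testis at postnatal day 12 (P12) and postnatal day 18 (P18), from wild-type (WT) males and from Alkbh5-null males (KO). Each of the 4 groups has 2 libraries, 8 in all. Per the labels, total RNA was extracted with TRIzol, samples with an RNA integrity number above 7 were used, poly(A) RNA was selected, the second strand was marked with dUTP, and 2 reads of 150 bp were taken per fragment on an Illumina NovaSeq. The labels do not state whether the libraries of a group come from separate animals, so the p-value of a single gene measures only the spread between these libraries. P-values for lists of genes compare genes with other genes, as described below, and do not measure that spread alone.

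The authors' processing notes name cutadapt 1.9, HISAT2 2.2.1, StringTie 2.1.6 and the mouse build GRCm38. The deposited table gives, for each of 38163 genes and each library, an FPKM value (fragments scaled by transcript length and by library depth) and a count. The deposited counts are whole numbers that sum to a different total in each library, and no normalization of them was found. Which tool made the counts, and whether strand was used in counting, is not stated, so genes that overlap another gene on the opposite strand, or that have near-identical copies, have uncertain values. Of the 38163 genes, 38000 are in GENCODE release M21, and 34935 of these have the same start and end there.

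Genes with an FPKM of at least 1 in at least 2 libraries were tested, 16702 in all. Samples were grouped by the genotype and age in their labels. 5 comparisons were made: KO against WT at P12, KO against WT at P18, P18 against P12 in WT, P18 against P12 in KO, and the genotype by age interaction, which is the KO change with age minus the WT change with age. Counts were scaled with the trimmed mean of M-values (TMM) and tested with the edgeR 4.0.16 quasi-likelihood F-test (R 4.3.3), with a mean for each group and 1 spread shared by the 4 groups, which leaves 4 residual degrees of freedom. All tests are two-sided. P-values were adjusted over all genes tested by the Benjamini-Hochberg method, and genes with an adjusted p under 0.05 were called. The standard error (SE) of a log2 fold change is its size divided by the square root of F.

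The comparisons, the filter, the gene lists, the rule for naming genes and most alternatives were chosen before the data were examined. The test planned then was limma on log2(FPKM + 1), because counts were not known to be in the table. As the table holds counts, edgeR became the test and limma 3.58.1 as planned became an alternative, as did DESeq2 1.42.0. These changes, a fit without the 2 P18 libraries whose Alkbh5 level goes against their label, a fit with the P18 libraries paired across replicate numbers, DESeq2 and limma fits of the 4 P12 libraries alone, and a list of 40 hepatocyte genes were chosen after the data were seen. The other alternatives cover the pseudocount, the filter, the scaling, the trend, sample weights, the replicate number as a term, a fold threshold, the groups in the fit, the correlation within a gene list, and leaving out each library in turn.

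Lists of genes were tested with camera (limma) on the edgeR fit with a preset correlation of 0.01 between genes, which compares a list with all other tested genes. Of 24 lists, 23 had at least 5 tested genes, and p-values were adjusted over these 23 within a comparison. The lists cover spermatogonia, pachytene and diplotene spermatocytes, spermatids, the synaptonemal complex with meiotic cohesin, meiotic recombination, regulators of the meiotic transcription programme, the piRNA pathway, the G2 and M phases, autosomal retrogenes of X-linked genes, N6-methyladenosine (m6A) machinery, DNA methylation enzymes, Sertoli, Leydig, peritubular and stromal, endothelial, red blood cell, macrophage and epididymis genes, p53 targets with apoptosis genes, immediate-early genes, mitochondrially encoded genes, X-linked housekeeping genes, Y-linked genes, and genes near Alkbh5. Some genes are in more than 1 list. All X-linked genes and all Y-linked genes were tested as a further pair of sets, and 1904 gene ontology terms with 10 to 300 tested genes were tested in the same way. Camera was repeated with a correlation estimated from the data, and fry (limma) was run beside it. In the fit of all 8 libraries that correlation comes from the differences within all 4 groups, whichever comparison is tested. Calls within a list were also counted with p-values adjusted over the list alone.

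Genes were named by this rule: Alkbh5 throughout, and in each comparison the 10 genes higher and the 10 lower with the largest fold change among those called, with a mean of at least 5 FPKM in the higher group, both libraries of 1 group above both of the other, and no predicted or clone name. Where fewer than 5 passed, the genes with the lowest p were added up to 5 and are said not to have passed. The interaction took 5 in each direction without the separation of libraries. From each list described, 2 to 4 members with the lowest p were chosen, but not all of them are named in the text.

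The procedure was tested on simulated data with the dispersions of these libraries, in which 200 of the 16702 genes were changed, 100 by 1 and 100 by 2 on the log2 scale. At P12 the edgeR fit of all 8 libraries called 0 and 1 of the 100 with 0 false calls, and at P18 it called 0 and 0. On the same P12 simulation DESeq2 called 9 and 70 with 122 false calls, 60.7% of its calls. Limma called 0 and 4 with 2 false calls, 33.3% of its calls. In these simulations of all 8 libraries each gene had the same spread in every group. The simulated P12 libraries so varied more than the real ones, whose common dispersion was 0.0179 alone and 0.226 with the P18 groups. With the 4 P12 libraries alone, edgeR called 79 and 97 with 17 false calls, 8.81% of its calls, and DESeq2 called 83 and 97 with 35 false calls. With the 6 libraries left without the doubted P18 pair, edgeR called 47 and 88 at P18 with 24 false calls, 15.1% of its calls. Camera called the list of simulated lower genes as lower (adjusted p = 1.4e-43) and 0 of 22 lists of unchanged genes. The simulated genes were drawn independently of each other, so this cannot show how often camera makes false calls on lists whose genes vary together. Counts were also drawn at the fitted spread of each gene, so the shares found need not hold in the real libraries. In edgeR on the real P12 libraries alone 9 genes were called. Of these Mroh4, at log2 -4.32 ± 0.41, reached an adjusted p of only 0.0467.

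Total counts ran from 58417668 to 71537841 per library. Folds against a library at 0 counts are given as lower bounds against a floor of 3 counts in that library, and such floors cover counting error only.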

Results

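Gene expression was measured by RNA-seq in whole testis of WT and Alkbh5-null mice at P12, when most spermatocytes are in leptotene and zygotene, and at P18, when most are in pachytene and diplotene. ALKBH5 removes the m6A mark from RNA, and the purpose stated for the series is to explore its function in spermatogenesis. There were 2 libraries in each of 4 groups. Total counts were 58732528 and 58417668 in the libraries labelled WT P12, 61315630 and 61533168 in KO P12, 62634844 and 59151494 in WT P18, and 66080256 and 71537841 in KO P18. The number of genes with at least 1 FPKM lay between 14429 and 15176 in each library. Across genes, the log2 FPKM of the libraries of a group correlated at r = 0.991 in WT P12, 0.989 in KO P12, 0.836 in WT P18 and 0.755 in KO P18. Across labels, r was 0.985 between WT P18 replicate 1 and KO P18 replicate 2. It was 0.968 between WT P18 replicate 2 and KO P18 replicate 1. The first principal component held 84.4% of the variance and placed WT P18 replicate 2 (86.6) and KO P18 replicate 1 (117.7) apart from the other 6 libraries (-48.5 to -20.9).

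Alkbh5 itself (ENSMUSG00000042650, chromosome 11, 60536381 to 60558512 on GRCm38) followed the labels at P12 and went against them in 1 library of each genotype at P18. The libraries labelled WT P12 had 10.2 and 17.8 FPKM (3888 and 6746 counts), and those labelled KO P12 had 0.0564 and 0.0218 FPKM (23 and 10 counts). At P18, the library labelled WT replicate 1 had 0.00985 FPKM (4 counts) and that labelled WT replicate 2 had 9.07 FPKM (3489 counts). The library labelled KO replicate 1 had 17.9 FPKM (7800 counts), above every library labelled WT, and that labelled KO replicate 2 had 0.155 FPKM (73 counts). As labelled, the log2 difference of KO from WT was -8.35 ± 3.52 (SE, n = 2 per group) at P12 and 1.19 ± 2.54 at P18, both with an adjusted p of 1 (edgeR quasi-likelihood). Within the 4 P12 libraries alone it was -8.37 ± 0.42 (adjusted p = 0.00466, edgeR). Each P18 group therefore holds 1 library with and 1 without the Alkbh5 transcript, so every direction drawn at P18 is that of the labels, which the Alkbh5 level contradicts in 2 libraries. Samples are named by their labels throughout.

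**Figure D1:**
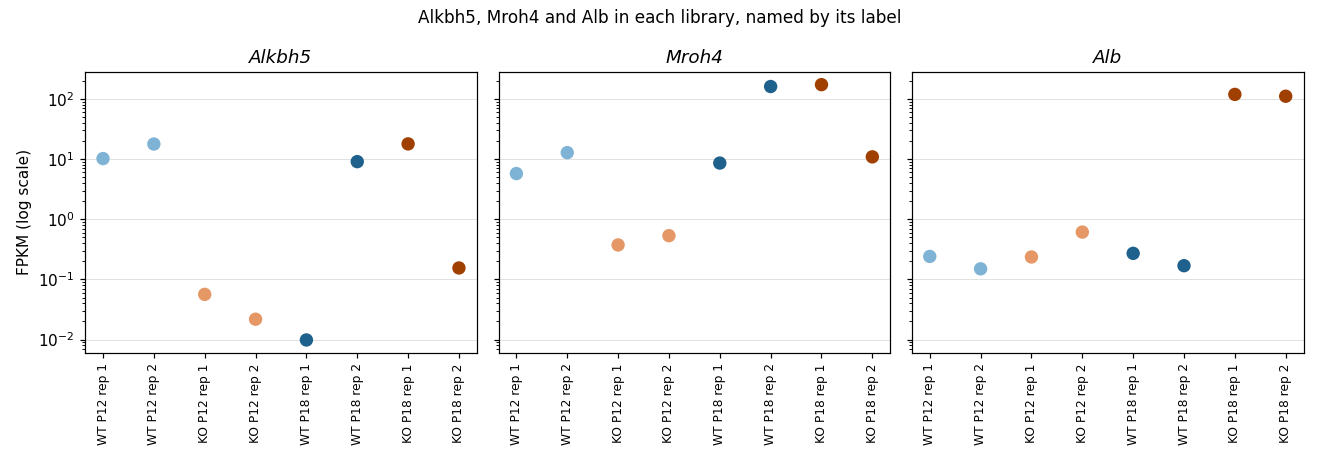
FPKM on a log axis of Alkbh5, Mroh4 and Alb in each of the 8 libraries, named by label, 1 point per library. At P18 Alkbh5 is at 17.9 in KO replicate 1 and 0.00985 in WT replicate 1, Mroh4 is at 161 and 173 only in the 2 libraries with Alkbh5, and Alb is at 119 and 111 only in the 2 libraries labelled KO P18.

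The comparison at P12 asks what the loss of Alkbh5 does while spermatocytes are in leptotene and zygotene. Transcripts of meiotic genes were lower in the testes labelled KO. Genes of recombination, of the synaptonemal complex and of its cohesins, and genes of pachytene and diplotene spermatocytes were lower as lists in camera, and Sertoli and Leydig cell genes were higher. With a correlation estimated from the data none of these 5 calls remained (adjusted p = 0.362 to 0.935), and without KO P12 replicate 1 the Leydig median was 0.07 (adjusted p = 0.395). That correlation was estimated from all 8 libraries. It includes the differences within the P18 groups, which are the largest, and so does not measure the spread at P12 alone. Both libraries labelled KO P12 had less Meiob (6.02 and 7.20 FPKM against 15.2 and 19.4 in WT), Sycp3 (77.0 and 107 against 144 and 158), Adam2 (0.522 and 0.563 against 2.83 and 5.39) and Piwil1 (1.32 and 1.82 against 4.35 and 9.98). Amh (41.8 and 58.9 against 35.2 and 29.7) and Dhh (33.5 and 41.3 against 29.8 and 25.9) were higher in both. In whole testis, a lower level can come from fewer cells of a type or from less transcript per cell, and these data do not separate the cases.

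The fit of all 8 libraries called 0 of 16702 genes with edgeR (131 at an unadjusted p under 0.05). DESeq2 called 11, 3 higher and 8 lower, and limma 0. That fit shares its spread with the P18 groups, whose libraries differ most, and its common dispersion was 0.226 against 0.0179 for the 4 P12 libraries alone. The latter called 9 genes, all lower in KO (2271 at an unadjusted p under 0.05). DESeq2 on the same 4 libraries called 659 (118 higher, 541 lower) and limma 0. Besides Alkbh5, the genes called that meet the naming rule were Mroh4 (ENSMUSG00000022603, chromosome 15), Gml (ENSMUSG00000068349, chromosome 15) and Cntd1 (ENSMUSG00000078653, chromosome 11). Mroh4 fell to 0.374 and 0.533 FPKM from 5.75 and 12.8 (log2 -4.32 ± 0.41, adjusted p = 0.0467). Gml fell to 7.38 and 8.30 from 25.5 and 38.5 (-2.01 ± 0.20, adjusted p = 0.0467), and Cntd1, a meiotic crossover gene, fell to 2.05 and 1.92 from 6.51 and 9.46 (-1.99 ± 0.19, adjusted p = 0.0467). The other 5 were named after their values were seen: 1700006A11Rik (-5.24), Morc2b (-4.34), Gm43951 (-2.54), Gm49794 (-2.44) and Gm10736 (-1.45). Of these 8 genes besides Alkbh5, 7 were also lower in the 2 P18 libraries without Alkbh5 than in the 2 with it, whatever their label, and Gm10736 was not. The share of all tested genes with that order was not counted. The first principal component (84.4% of the variance) parts the same P18 libraries, so the order of these genes is no separate evidence. Ly6k (-1.11, adjusted p = 0.0532), Meiob (-1.37 ± 0.16, adjusted p = 0.0532) and Adam2 (-2.90 ± 0.33, adjusted p = 0.0532) missed the threshold there. No gene was called higher, and Rpl17 (0.92), Kitl (0.41), Epha2 (0.77), Pdlim4 (0.49) and Gja1 (0.35), which had the lowest p among the higher genes, did not pass. In the fit of all 8 libraries the lowest p among genes that did not pass belonged, on the higher side, to Epha2 (0.78 ± 0.23), Tigd2 (0.53 ± 0.17), Rpl17 (0.93 ± 0.30), Bambi (0.48 ± 0.16) and Eef2-ps2 (0.83 ± 0.29). On the lower side they were Rps27a-ps2 (-2.09 ± 0.29), Tpbgl (-2.0 ± 0.32), H2-K1 (-0.61 ± 0.11), Bloc1s4 (-1.07 ± 0.22) and Rad51ap2 (-0.85 ± 0.20), all with an adjusted p of 1. The pseudogenes, the ribosomal gene and H2-K1 share reads with near-identical copies.

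The lists at P12, tested with camera on all 8 libraries, gave 9 of 23 past the threshold. The 32 recombination genes fell with a median log2 difference of -0.40 (31 of 32 lower, adjusted p = 4.34e-15), led by Prdm9 (-0.62 ± 0.23) and Meiob (-1.35 ± 0.56). With an estimated correlation the adjusted p was 0.362. The 19 synaptonemal complex and cohesin genes fell by 0.404 (17 of 19 lower, adjusted p = 1.35e-08, and 0.538 with an estimated correlation), among them Hormad2 (-0.86 ± 0.39) and Sycp3 (-0.69 ± 0.37). The 28 pachytene and diplotene genes fell by 0.741 (26 of 28 lower, adjusted p = 1.58e-07, and 0.935 with an estimated correlation), with Adam2 at -2.88 ± 1.88 and Sox30 at -1.14 ± 0.84. Regulators of the meiotic programme fell by 0.370 (20 of 24 lower, adjusted p = 7.09e-06, and 0.362 with an estimated correlation), Ythdc2 among them (-0.49 ± 0.23), along with Prdm9, which is in both lists. The piRNA pathway (median -0.25, adjusted p = 0.00823; Mov10l1 at -0.56 ± 0.35 and Piwil1 at -2.16 ± 1.79), the autosomal retrogenes (-0.39, adjusted p = 0.0115; Tktl2 at -1.21 ± 0.68 and Pgk2, which has 0 or a few counts here) and G2 and M phase genes (-0.12, adjusted p = 0.0121; Bub1 at -0.43 ± 0.18 and Top2a at -0.39 ± 0.23) were also lower, each at 0.935 with an estimated correlation. Sertoli genes rose by 0.251 (23 of 25 higher, adjusted p = 0.000685; Amh 0.66 ± 0.45 and Dhh 0.45 ± 0.34) and Leydig genes by 0.261 (14 of 15 higher, adjusted p = 0.00936; Cyp11a1 0.51 ± 0.28 and Insl3 0.78 ± 0.59), both at 0.935 with an estimated correlation. Without KO P12 replicate 1, 5 of these calls were lost: regulators (-0.32, adjusted p = 0.0532), retrogenes (-0.50, adjusted p = 0.0558), piRNA (-0.22, adjusted p = 0.149), G2 and M phase (-0.11, adjusted p = 0.282) and Leydig (0.07, adjusted p = 0.395). The number of lists past the threshold was then 5, while without WT P12 replicate 1 it was 12.

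Over all genes, 0 members of these lists were called at P12 in the fit of all 8 libraries by edgeR, and 0 when adjusted over the list alone. In the 4 P12 libraries alone, adjusted over the list alone, 17 pachytene, 15 recombination, 12 synaptonemal and 12 piRNA genes were lower, with 13 regulators, 5 retrogenes and 3 G2 and M phase genes. Over all genes only Cntd1 among the recombination genes was. In the same fit, 7 Sertoli genes were higher, adjusted over the list alone, among the lowest p Inha (0.37, adjusted p over all genes 0.109), and 1 regulator was higher. The m6A machinery had 1 gene higher and 1 lower there. It did not differ as a list (median -0.01, adjusted p = 0.649), and its lowest p belonged to Igf2bp2 (0.70 ± 0.26) and Ythdc2. Spermatogonial genes (0.11, adjusted p = 0.086), mitochondrially encoded genes (0.10, adjusted p = 0.0929), X-linked housekeeping genes (0.10, adjusted p = 0.127), immediate-early genes (0.18, adjusted p = 0.331), endothelium (0.18, adjusted p = 0.337), DNA methylation enzymes (0.13, adjusted p = 0.44), Y-linked genes (0.07, adjusted p = 0.623), peritubular genes (-0.02, adjusted p = 0.672), p53 targets (0.02, mean -0.03, adjusted p = 0.672), genes near Alkbh5 (0.03, adjusted p = 0.728), macrophages (0.02, adjusted p = 0.84), red blood cells (-0.03, adjusted p = 0.929) and spermatids (-0.01, adjusted p = 0.929) did not pass. Single libraries turned some of these into calls. Macrophage genes were called higher without KO P12 replicate 2 (0.37, adjusted p = 0.00279) and lower without KO P12 replicate 1 (-0.41, adjusted p = 0.000117). Red blood cell genes were called higher without WT P12 replicate 2 (0.42, adjusted p = 0.000817) and lower without WT P12 replicate 1 (-0.38, adjusted p = 0.00294). Spermatogonial genes were called without WT P12 replicate 1 (0.23) and without either library labelled KO P18 (0.11). The same held for mitochondrially encoded genes without WT P12 replicate 2 (0.13) or KO P12 replicate 2 (0.24), peritubular genes without WT P12 replicate 1 (-0.135) and X-linked housekeeping genes without KO P18 replicate 1 (0.10). Only Cst11 (0.38 ± 0.54) and Cst8 (0.24 ± 0.50) of the epididymis genes were tested. The 673 X-linked genes were slightly higher as a set (0.11, 476 of 673 higher, adjusted p = 0.00828, and 0.731 with an estimated correlation), a call lost without WT P12 replicate 2 (0.10, adjusted p = 0.0576) or KO P12 replicate 1 (0.09, adjusted p = 0.0513), and the 28 Y-linked genes were not shown to differ (0.12, adjusted p = 0.222). Of 1904 gene ontology terms, 27 passed, led by synapsis (32 genes, median -0.34, adjusted p = 6.76e-10), with 8 higher and 19 lower. None passed with an estimated correlation, where synapsis had an adjusted p of 0.998. In camera on the 4 P12 libraries alone 99 terms passed, 19 higher and 80 lower, and 0 passed with an estimated correlation.

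**Figure D2:**
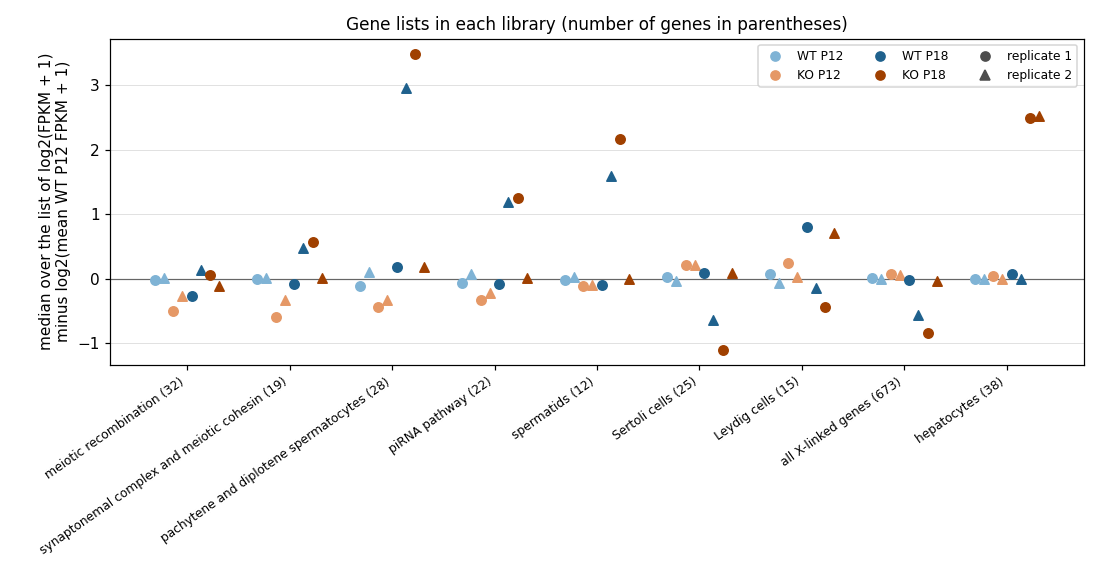
For 9 gene lists, the median over the list of log2(FPKM + 1) minus log2 of the mean WT P12 FPKM + 1, 1 point per library (colour for the labelled group, shape for the replicate). In pachytene and diplotene genes WT P18 replicate 2 and KO P18 replicate 1 sit at 2.95 and 3.49 and the other P18 libraries at 0.19 and 0.18, while hepatocyte genes sit at 2.49 and 2.52 in the 2 libraries labelled KO P18 and between 0 and 0.07 in the other 6.

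The comparison at P18 asks the same of testes in which pachytene and diplotene spermatocytes have appeared. Late-prophase genes did not follow the labels. They were high in the 2 libraries with the Alkbh5 transcript, 1 of each label, and much lower in the 2 without it, where the pachytene list (0.187 and 0.184 by library) was a little above WT P12 (-0.11 and 0.102) and further above KO P12 (-0.445 and -0.336). Ybx2 had 47.3 FPKM in WT replicate 1, 408 in WT replicate 2, 520 in KO replicate 1 and 48.4 in KO replicate 2. In the same order Piwil1 had 7.75, 193, 203 and 11.1 FPKM, Adam2 4.65, 100, 128 and 5.05, Pgk2 0.406, 24.3, 58.7 and 0.377, and the P12 gene Mroh4 8.59, 161, 173 and 10.9. Red blood cell genes did follow the labels, with list medians against WT P12 of 1.264 and 0.813 in WT P18 and 0.472 and 0.257 in KO P18. A larger difference that followed the labels was in transcripts typical of liver. Alb (ENSMUSG00000029368) had 119 and 111 FPKM in the libraries labelled KO P18 and 0.15 to 0.612 in the other 6, and Apoa1 had 25.8 and 25.5 FPKM against 0.101 to 0.224. Ybx2, Adam2, Piwil1 and Pgk2 are quoted here after their values were seen.

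As labelled, edgeR called 0 genes at P18 (189 at an unadjusted p under 0.05), where DESeq2 called 76 (71 higher, 5 lower) and limma on FPKM 27. Those nearest to the threshold were liver transcripts. Alb (log2 9.13 ± 0.66, adjusted p = 0.0984), Apoa1 (7.53 ± 0.57, adjusted p = 0.0984), Gnmt (3.51 ± 0.30, adjusted p = 0.127) and Cyp2e1 (3.13 ± 0.29, adjusted p = 0.148) did not pass, nor did Fga, which had 5.15 and 8.17 FPKM in the libraries labelled KO against 0.0380 and 0.0205. On the lower side, genes among those with the lowest p were Gpx3 (-1.74 ± 0.33, adjusted p = 0.674), Rpl41 (-0.94 ± 0.28), Hbb-bs (-0.75 ± 0.24) and CT010467 (-0.74 ± 0.23), the last 3 with an adjusted p of 1. Rpl41 and Hbb-bs share reads with copies, and the annotation gives no description of CT010467.

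Of the lists at P18, 8 of 23 passed as labelled in camera. With an estimated correlation none did, and the adjusted p was 0.67 for m6A and red blood cell genes and 0.835 for the other 6. Peritubular and stromal genes fell by 0.247 (17 of 17 lower, adjusted p = 1.16e-06; Dpt -0.81 ± 0.35 and Lum -1.0 ± 0.54) and red blood cell genes by 0.647 (5 of 5 lower, adjusted p = 1.16e-06; Hbb-bs and Hbb-bt at -0.83 ± 0.33). Mitochondrially encoded genes (0.18, adjusted p = 0.00127; mt-Atp8 0.26 ± 0.15 and mt-Nd4l 0.27 ± 0.18), G2 and M phase genes (0.24, adjusted p = 0.00174; Plk1 1.01 ± 0.46 and Cenpe 0.50 ± 0.34), the m6A machinery (0.13, adjusted p = 0.0287; Ythdc1 0.32 ± 0.11 and Rbm15 0.28 ± 0.23) and pachytene genes (0.62, adjusted p = 0.0387; Cdc25c 0.21 ± 0.19 and Mybl1 0.47 ± 0.48) rose. Endothelium (-0.16, adjusted p = 0.0287; Tie1 -0.44 ± 0.29 and Egfl7 -0.42 ± 0.30) and macrophages (-0.26, adjusted p = 0.0287; C1qc -0.56 ± 0.35 and Lyz2 -0.52 ± 0.39) fell. Single libraries set most of these directions. Without KO P18 replicate 1 the pachytene median was -2.27, G2 and M phase -0.06, peritubular 0.04, endothelium 0.03, macrophages 0.04 and m6A 0.11, and only the pachytene list of these passed, as lower. Omitting WT P18 replicate 1 left endothelium at 0.18, macrophages at 0.09, peritubular at -0.16, G2 and M phase at 0.07 and m6A at 0.10, all uncalled. The pachytene list was then called lower at a median of 0.025. Red blood cell genes (-0.39), mitochondrially encoded genes (0.05) and m6A (0.10) were not called without KO P18 replicate 2. Nor were mitochondrially encoded genes (0.05) and m6A (0.11) without WT P18 replicate 2, while the pachytene median was 2.94 and 17 lists passed. With replicate number as a block the pachytene list was not called (0.775, adjusted p = 0.0762). Plk1 was high in 1 library only: 10.9 and 11.3 FPKM in the libraries labelled WT, 27.4 in KO replicate 1 and 12.6 in KO replicate 2.

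The other lists at P18 did not pass as labelled: spermatids (0.77, adjusted p = 0.158; Fndc3a 0.50 ± 0.41 and Odf2 0.81 ± 0.94), regulators (0.34, adjusted p = 0.281; Dmrtb1 1.08 ± 1.15), retrogenes (0.24, adjusted p = 0.258; Utp14b 0.46 ± 0.27), the synaptonemal complex (0.17, adjusted p = 0.343; Sycp1 0.34 ± 0.32), immediate-early genes (0.16, adjusted p = 0.258), piRNA (0.16, adjusted p = 0.624), recombination (0.10, adjusted p = 0.504), genes near Alkbh5 (-0.04, adjusted p = 0.233), Leydig (-0.05, mean 0.01, adjusted p = 0.784), X-linked housekeeping (-0.06, adjusted p = 0.139), DNA methylation (-0.07, adjusted p = 0.449), p53 targets (-0.07, adjusted p = 0.258), spermatogonia (-0.08, adjusted p = 0.152), Sertoli (-0.13, adjusted p = 0.227; Trf 1.06 ± 0.36 and Aard 1.05 ± 0.36) and Y-linked genes (-0.16, adjusted p = 0.158). Most of these were called when 1 library was left out, in a direction that depended on which. Spermatids (-2.07, adjusted p = 0.0017), retrogenes (-0.98) and piRNA genes (-0.75) were called lower without KO P18 replicate 1. Called higher in that fit were Leydig (0.34), Sertoli (0.23), spermatogonial (0.23), X-linked housekeeping (0.27) and immediate-early genes (0.51). Omitting WT P18 replicate 1 made piRNA (-0.30), recombination (-0.15) and synaptonemal genes (-0.15) lower. Leydig (0.37), Sertoli (0.24), X-linked housekeeping (0.26) and immediate-early genes (0.53) were then higher. The signs were the other way without WT P18 replicate 2: spermatids (2.63), retrogenes (0.95), piRNA (1.22), regulators (0.91), recombination (0.51) and synaptonemal genes (0.62) were called higher. Leydig (-0.38), Sertoli (-0.45), spermatogonial (-0.31), X-linked housekeeping (-0.30) and Y-linked genes (-0.37) were called lower there. Omitting KO P18 replicate 2 made spermatids (1.64), retrogenes (0.88), piRNA (0.78) and synaptonemal genes (0.43) higher. Lower in that fit were Leydig (-0.63), Sertoli (-0.66), spermatogonial (-0.50), X-linked housekeeping (-0.51), Y-linked (-0.44), p53 (-0.40) and immediate-early genes (-0.38). In the 23 lists, 0 members were called over all genes or adjusted over the list alone (edgeR). The X-linked genes as a set fell by 0.093 (adjusted p = 2.7e-05, and 0.633 with an estimated correlation), but were called higher without WT P18 replicate 1 (0.22, adjusted p = 1.15e-05) and without KO P18 replicate 1 (0.21, adjusted p = 8.98e-11). By library their median against WT P12 was -0.02 and -0.57 in WT P18 and -0.85 and -0.04 in KO P18, so it was low in the same 2 libraries in which late-prophase genes were high. Of the gene ontology terms 31 passed, led by steroid hydroxylase activity (10 genes, median 5.81, adjusted p = 2.17e-30, and 0.254 with an estimated correlation), where hepatocyte genes were at 6.24 and Leydig genes at -0.05, with structural constituents of the ribosome lowest (157 genes, -0.11, adjusted p = 1.26e-08, and 1 with an estimated correlation).

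Leaving out the 2 P18 libraries whose Alkbh5 level goes against their label gives a fit of 6 libraries, with 1 library in each P18 group that is assumed to vary like the P12 groups. The libraries were left out for their Alkbh5 level, which fixes the direction of Alkbh5 itself (-5.98), so that value is no evidence. EdgeR called 6357 genes at P18 in this fit, 2610 higher and 3747 lower. Pachytene and diplotene genes had a median of -3.11, spermatids -2.87, retrogenes -1.52, piRNA genes -1.30, recombination genes -0.44 and the synaptonemal complex -0.55. Sertoli genes were at 0.60, Leydig genes at 0.75 and X-linked genes at 0.54. Among the 10 lower genes with the largest folds were Ldhal6b, Speer1 and Ms4a19, each with 0 counts in KO P18 replicate 2. Against a floor of 3 counts in that library they were at least 2900-fold, 464-fold and 108-fold lower than in WT P18 replicate 2. Cmtm2b (84.3 against 0.465 FPKM), Adam18 (16.7 against 0.123) and Actl7b (19.1 against 0.193) were others. The higher genes with the largest folds were liver transcripts, such as Alb (9.18 ± 0.59, adjusted p = 0.000636), Serpina1c (8.91 ± 0.91, adjusted p = 0.00322), which has near-identical copies, and Gc, with 14.0 FPKM against 0. With no P18 group replicated, this fit measures the contrast between 1 pair of libraries.

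The change from P12 to P18 in WT asks how the testis changes normally as pachytene spermatocytes appear. It cannot be read as such from the labels, because the library labelled WT P18 replicate 1 is without the Alkbh5 transcript (4 counts). The 2 libraries labelled WT P18 differed in most lists. Leydig genes were at 0.796 in replicate 1 and -0.142 in replicate 2 against WT P12, Sertoli genes at 0.092 and -0.636, and macrophage genes at 0.868 and 0.106. A few genes picked after their values were seen, none past the threshold, had similar levels in both: Ano1 had 9.17 and 9.60 FPKM at P18 against 3.08 and 3.48 at P12, Zbtb46 2.85 and 2.21 against 7.24 and 7.01, and Dlk1 3.81 and 2.15 against 12.5 and 11.9. The Leydig gene Insl3 had 94.8 and 37.6 FPKM against 11.9 and 14.8. Spermatocyte genes were far higher in replicate 2 than in replicate 1: Pgk2 had 24.3 FPKM and 0.406 FPKM, against 0.209 and 0.192 at P12.

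In edgeR 0 genes were called (1082 at an unadjusted p under 0.05), in DESeq2 408 (283 higher, 125 lower) and in limma 0. The lowest p among higher genes, none past the threshold, belonged to Ano1 (1.63 ± 0.15, adjusted p = 0.288), Dmrtc1b (2.82 ± 0.36), Trpc5os (3.54 ± 0.46), Scd1 (2.21 ± 0.30) and Reep6 (1.45 ± 0.23). Among lower genes it belonged to Zbtb46 (-1.38 ± 0.19), Rps27a-ps2 (-1.89 ± 0.29), Lrrc17 (-1.25 ± 0.21), Gcat (-0.97 ± 0.17) and Dlk1 (-1.93 ± 0.35), and the adjusted p of all these but Ano1 was 0.614. Trpc5os lies antisense to another gene, and Alkbh5 itself was at -1.44 ± 2.56 (adjusted p = 0.827). As lists, 8 of 23 passed, each at an adjusted p of 0.794 with an estimated correlation. Red blood cell genes rose by 1.19 (5 of 5 higher, adjusted p = 1.69e-06; 5 called when adjusted over the list alone, 0 over all genes), with Hbb-bs at 1.03 ± 0.24 and Hba-a1 at 1.25 ± 0.31. Pachytene genes rose by 2.35 (26 of 28 higher, adjusted p = 0.000118; Adam3 had 1.18 and 70.7 FPKM at P18, while Cdc25c was at -0.82 ± 0.19), macrophage genes by 0.722 (adjusted p = 0.000582; Cd74 1.61 ± 0.44 and Mrc1 1.07 ± 0.35), piRNA genes by 0.871 (adjusted p = 0.0203; Tdrd6 5.86 ± 2.61 and Piwil1 3.99 ± 1.92), Leydig genes by 0.471 (adjusted p = 0.0241; Insl3 2.40 ± 0.62 and Hsd3b6 3.32 ± 0.89) and spermatid genes by 2.07 (adjusted p = 0.0241; Spaca1 1.13 ± 0.29). X-linked housekeeping genes fell by 0.189 (adjusted p = 0.0118; Rpl10 -0.51 ± 0.28 and Zfx -0.38 ± 0.23) and spermatogonial genes by 0.307 (adjusted p = 0.0144; Gfra1 -1.15 ± 0.28 and Crabp1 -0.87 ± 0.26). The 673 X-linked genes fell by 0.218 (adjusted p = 4.85e-07, and 0.519 with an estimated correlation) and the 28 Y-linked genes by 0.390 (adjusted p = 0.000277, and 0.519 with an estimated correlation). Without WT P18 replicate 2 the pachytene list was at 0.30 and not called (adjusted p = 0.66), nor were piRNA genes (-0.05), spermatids (-0.15), X-linked housekeeping genes (0.03) and spermatogonia (-0.03), and all X-linked genes were at 0.02 and not called (adjusted p = 0.627). With WT P18 replicate 1 left out, 14 lists passed and the pachytene median was 3.165, but Leydig (-0.01) and macrophage genes (0.34) were not called. The Leydig call was also lost without KO P18 replicate 1 (0.47, adjusted p = 0.0503) and without KO P18 replicate 2 (0.47, adjusted p = 0.0593).

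Lists that did not pass in WT were retrogenes (0.98, adjusted p = 0.121), regulators (0.37, adjusted p = 0.381; Stra8 -0.59 ± 0.25 and Rfx2 2.62 ± 1.35), the synaptonemal complex (0.36, adjusted p = 0.158), genes near Alkbh5 (0.11, adjusted p = 0.545), recombination (0.06, adjusted p = 0.73), G2 and M phase (0.03, adjusted p = 0.31; Ccnb1 -0.67 ± 0.15), m6A (0.02, adjusted p = 0.958), mitochondrially encoded genes (-0.04, adjusted p = 0.381), peritubular genes (-0.11, adjusted p = 0.292), p53 targets (-0.12, mean 0.14, adjusted p = 0.826; Cdkn1a 1.52 ± 0.33), Sertoli genes (-0.13, adjusted p = 0.292), DNA methylation (-0.20, adjusted p = 0.292), endothelium (-0.21, adjusted p = 0.121), immediate-early genes (-0.25, adjusted p = 0.114) and Y-linked genes (-0.35, adjusted p = 0.158). Sertoli genes were called higher without WT P18 replicate 2 (0.14, adjusted p = 0.0267) and recombination (-0.26) and G2 and M phase genes (-0.28) lower. Retrogenes (1.45) and synaptonemal genes (0.66) were called higher without WT P18 replicate 1. Lower in that fit were Sertoli (-0.47), Y-linked (-0.64), endothelial (-0.615), immediate-early (-0.40), peritubular (-0.28) and mitochondrially encoded genes (-0.19). Peritubular genes were also called without WT P12 replicate 1 (-0.25). Gene ontology terms past the threshold numbered 51, with motile cilium rising (105 genes, median 1.96, adjusted p = 2.49e-07) and the cytosolic large ribosomal subunit falling (53 genes, -0.33, adjusted p = 6.89e-09), both at an adjusted p of 1 with an estimated correlation.

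The same change in KO asks whether the testis moves through prophase without Alkbh5. It cannot be read as such from the labels, because the library labelled KO P18 replicate 1 has the Alkbh5 transcript and that labelled replicate 2 does not. Late-prophase genes were up far more in replicate 1 than in replicate 2, as with Adam2 at 128 and 5.05 FPKM against 0.522 and 0.563 at P12. Among genes picked after their values were seen, none past the threshold, Ano1 had 7.12 and 8.80 FPKM against 2.29 and 2.27, H19 5.22 and 10.2 against 27.9 and 32.7, and Zbtb46 1.9 and 3.16 against 7.74 and 7.75. Liver transcripts were up in both.

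EdgeR called 0 genes in KO (3180 at an unadjusted p under 0.05), DESeq2 2381 (1766 higher, 615 lower) and limma 31. Nearest to the threshold on the higher side were Cyp2e1 (4.84 ± 0.31, adjusted p = 0.0566), Hp (5.00 ± 0.33, adjusted p = 0.0566), Apoa1 (7.46 ± 0.57), Alb (8.27 ± 0.64) and Ano1 (1.97 ± 0.16), the last 3 at an adjusted p of 0.0589. On the lower side they included Epha2 (-2.04 ± 0.24), Rps16 (-1.08 ± 0.13), Zbtb46 (-1.46 ± 0.19) and H19 (-1.84 ± 0.24), each at an adjusted p of 0.169, while Alkbh5 was at 8.10 ± 3.49 (adjusted p = 0.263). Hp also had 4.03 and 4.2 FPKM in the libraries labelled WT P18, against 0.240 and 0.275 in WT P12. Of the lists, 14 passed, with an adjusted p of 0.653 at an estimated correlation, and 0.677 for Sertoli genes. Those that rose were pachytene genes (4.2, adjusted p = 1.12e-05; Sox30 3.31 ± 0.90 and Mybl1 1.80 ± 0.50), the synaptonemal complex (1.02, adjusted p = 0.00108; Sycp1 1.20 ± 0.32 and Hormad1 1.66 ± 0.47), piRNA genes (1.46, adjusted p = 0.00562), recombination (0.66, adjusted p = 0.00562; Msh4 1.95 ± 0.57 and Meiob 1.94 ± 0.57), regulators (1.14, adjusted p = 0.0167; Ythdc2 0.88 ± 0.23), retrogenes (1.87, adjusted p = 0.0194; Tktl2 2.43 ± 0.71), spermatids (2.60, adjusted p = 0.023; Zpbp 3.77 ± 1.35) and red blood cells (0.51, adjusted p = 0.0389; Alas2 1.30 ± 0.43). Spermatogonia (-0.51, adjusted p = 0.00108; Crabp1 -1.23 ± 0.26), X-linked housekeeping genes (-0.35, 23 of 23 lower, adjusted p = 0.00108; Rpl10 -1.03 ± 0.28), Sertoli genes (-0.56, adjusted p = 0.00709; Rhox8 -0.95 ± 0.32), endothelium (-0.66, adjusted p = 0.00735; Egfl7 -0.79 ± 0.30), peritubular genes (-0.28, adjusted p = 0.0125; Tcf21 -1.36 ± 0.28 and Dpt -1.69 ± 0.35) and Y-linked genes (-0.51, adjusted p = 0.0432) fell. Adjusted over the list alone, 2 peritubular genes were lower, and 1 Sertoli, 1 macrophage and 1 p53 gene were higher, against 0 over all genes. The Sertoli gene was Trf, at 23.8 and 38.1 FPKM in KO P18 against 7.21 and 5.76 in KO P12. Trf is also among the hepatocyte genes. Without KO P18 replicate 1 only 6 lists passed and the pachytene median was 1.3. The calls lost were those of spermatids (-0.14), X-linked housekeeping genes (-0.03), spermatogonia (-0.17), Sertoli genes (-0.17), Y-linked genes (-0.22), endothelium (-0.39), peritubular genes (0.004), retrogenes (0.33), piRNA genes (0.34) and red blood cells (0.36). Without KO P12 replicate 1 recombination (0.60), regulators (0.98) and peritubular genes (-0.225) were not called, and without KO P12 replicate 2 Y-linked (-0.50) and red blood cell genes (0.48) were not. The red blood cell call was also lost without KO P18 replicate 2 (0.70) and without WT P18 replicate 1 (0.51) or replicate 2 (0.51). The X-linked genes fell by 0.387 (551 of 673 lower, adjusted p = 1.38e-10, and 0.421 with an estimated correlation) and the Y-linked genes by 0.529 (adjusted p = 0.000195, and 0.421 with an estimated correlation).

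In KO, the lists that did not pass were G2 and M phase (0.48, adjusted p = 0.119), Leydig (0.47, adjusted p = 0.355; Hsd17b3 -1.49 ± 0.41 and Hsd3b6 2.98 ± 0.87), macrophages (0.29, adjusted p = 0.0774; Cd74 2.37 ± 0.45), m6A (0.16, adjusted p = 0.166), genes near Alkbh5 (0.12, adjusted p = 0.875), mitochondrially encoded genes (0.01, adjusted p = 0.875), p53 targets (-0.12, mean 0.12, adjusted p = 0.968; Cdkn1a 1.88 ± 0.34), immediate-early genes (-0.17, adjusted p = 0.211) and DNA methylation (-0.54, adjusted p = 0.133). Macrophage genes were called without KO P12 replicate 1 (0.86) or KO P18 replicate 1 (0.54), Leydig genes without KO P18 replicate 1 (0.75), and G2 and M phase (0.71) and immediate-early genes (-0.785) without KO P18 replicate 2. Motile cilium rose (3.15, adjusted p = 2.41e-09, and 0.998 with an estimated correlation) among 96 gene ontology terms past the threshold.

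The interaction asks whether the change with age differs between genotypes. It inherits the mixed P18 groups, so its directions are those of the labels. Meiob had 6.02 and 7.20 FPKM in KO P12, and 29.4 and 13.2 in KO P18, against 14.4 and 25.7 in WT P18. In edgeR 0 genes were called (160 at an unadjusted p under 0.05), in DESeq2 45 (40 higher, 5 lower) and in limma 7. Apoa1 (7.51 ± 0.70, adjusted p = 0.237), Alb (8.0 ± 0.77, adjusted p = 0.237), Gnmt (3.65 ± 0.40, adjusted p = 0.372) and Cyp2e1 (3.47 ± 0.39, adjusted p = 0.372) had the lowest p with Fga, and none passed. Among lower values Gpx3 (-2.04 ± 0.46), Rpl17 (-1.74 ± 0.42), Rpl41 (-1.43 ± 0.40), Ifi27l2a (-1.67 ± 0.49) and Epb41l4aos (-1.25 ± 0.40) did not pass either, each with an adjusted p of 1. Epb41l4aos is an antisense gene. Of the 23 lists 14 passed and 0 members were called, over all genes or adjusted over the list alone. Recombination (0.61, adjusted p = 1.2e-07, and 0.542 with an estimated correlation; Prdm9 0.68 ± 0.32) and pachytene genes (1.57, 28 of 28 positive, adjusted p = 1.35e-06, and 0.698 with an estimated correlation; Sox30 1.68 ± 1.17) had the lowest p on the positive side. Without KO P18 replicate 1 the pachytene value was -1.05, and without WT P18 replicate 1 only 6 lists passed. The lists that did not pass were Leydig (-0.30, adjusted p = 0.0536), Y-linked genes (-0.20, adjusted p = 0.134), macrophages (-0.29, adjusted p = 0.142), spermatids (0.71, adjusted p = 0.239), DNA methylation (-0.20, adjusted p = 0.239), mitochondrially encoded genes (0.08, adjusted p = 0.239), genes near Alkbh5 (-0.07, adjusted p = 0.239), p53 targets (-0.07, adjusted p = 0.669) and immediate-early genes (0.02, adjusted p = 0.946). Spermatids were called negative without KO P18 replicate 1 (-1.68, adjusted p = 0.00279) and positive without WT P18 replicate 2 (2.45) or KO P18 replicate 2 (1.395). Immediate-early genes were called negative without KO P18 replicate 2 (-0.54) and positive without WT P18 replicate 1 (0.34) or KO P18 replicate 1 (0.42). Leydig, macrophage and Y-linked genes were called without WT P18 replicate 2 (-0.62, -0.63 and -0.58) or KO P18 replicate 2 (-0.89, -0.69 and -0.63). Leydig genes were also called without WT P12 replicate 1 (-0.37), and Leydig (-0.27) and macrophage genes (-0.645) without KO P12 replicate 2. Mitochondrially encoded genes were called without KO P12 replicate 1 (0.22), WT P18 replicate 1 (0.29) or KO P18 replicate 1 (0.20). Of the gene ontology terms 49 passed, and none did with an estimated correlation in this or any other comparison.

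A last question is whether genes changed at P18 follow the normal change with age. The labels do not let it be answered, since WT P18 replicate 1 is without the Alkbh5 transcript and KO P18 replicate 1 has it. Across the 16702 genes, which are not independent replicates, the P18 difference of KO from 1 WT library was correlated with the change from P12 to the other WT library. With WT P18 replicate 1 as the control, r was 0.837 (covariance 0.487), and with WT P18 replicate 2 as the control it was 0.0517 (covariance 0.00772). The mean was 0.444, and r was 0.272 with both WT libraries on both sides. In that last value the WT P18 libraries enter the 2 differences with opposite signs, so without any relation it need not be 0. The KO effects at P12 and at P18 correlated at r = -0.188 across genes. Without WT P18 replicate 1 this r was 0.40, and without WT P18 replicate 2 it was -0.440. Genes called at both ages numbered 0 in edgeR, which was fixed by the 0 calls at each age and does not bear on how the effects relate.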

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

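All tests of explanations in this part were chosen only after the results were seen, while the interaction test of each list, hepatocytes excepted, was planned.

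In 16 sets of genes the KO effect at P18 differed from that at P12 by the interaction test (camera on the edgeR fit), with directions at P18 as labelled. Each is given with its interaction median and then its medians at P12 and P18. Pachytene and diplotene genes were at 1.57 (-0.74 and 0.62; adjusted p = 1.35e-06), regulators of the meiotic programme at 0.70 (-0.37 and 0.34; adjusted p = 0.000355), recombination at 0.61 (-0.40 and 0.10; adjusted p = 1.2e-07), retrogenes at 0.59 (-0.39 and 0.24; adjusted p = 0.0143), the synaptonemal complex at 0.58 (-0.40 and 0.17; adjusted p = 2.89e-05), G2 and M phase at 0.43 (-0.12 and 0.24; adjusted p = 0.000112), piRNA at 0.41 (-0.25 and 0.16; adjusted p = 0.0347) and the m6A machinery at 0.14 (-0.01 and 0.13; adjusted p = 0.0438). On the negative side were red blood cells at -0.65 (-0.03 and -0.65; adjusted p = 0.000861), Sertoli genes at -0.41 (0.25 and -0.13; adjusted p = 0.00241), endothelium at -0.35 (0.18 and -0.16; adjusted p = 0.0194), peritubular genes at -0.27 (-0.02 and -0.25; adjusted p = 0.00272), spermatogonia at -0.19 (0.11 and -0.08; adjusted p = 0.0233), X-linked housekeeping genes at -0.17 (0.10 and -0.06; adjusted p = 0.026) and all X-linked genes at -0.19 (0.11 and -0.09; adjusted p = 4.07e-06). Hepatocyte genes, a list written after albumin had been seen, were at 4.52 (0.32 and 6.24; adjusted p = 2.46e-69). With an estimated correlation the hepatocyte genes had an adjusted p of 0.000172. The other sets then lay between 0.542 and 0.756 and did not pass.

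Most of these values rest on the P18 libraries whose label the Alkbh5 level contradicts. Without KO P18 replicate 1 the values were -1.05 for pachytene genes, -0.67 for retrogenes, -0.43 for piRNA, -0.03 for regulators, -0.02 for peritubular genes, -0.01 for Sertoli genes, 0.02 for endothelium, 0.08 for G2 and M phase, 0.14 for spermatogonia, 0.16 for X-linked housekeeping genes and 0.11 for all X-linked genes. Of these, pachytene genes (adjusted p = 0.0302), X-linked housekeeping genes (adjusted p = 0.0112) and all X-linked genes (adjusted p = 3.19e-05) were then called with the opposite sign, and the others were not called. Without WT P18 replicate 1 the pachytene value was 0.81, retrogenes 0.36, the synaptonemal complex 0.20, X-linked housekeeping genes 0.14, m6A 0.12, spermatogonia 0.10, Sertoli genes 0.03, piRNA 0.003, endothelium -0.07 and peritubular genes -0.11, none past the threshold, while all X-linked genes were called with the opposite sign (0.13, adjusted p = 0.0429). The m6A call was also lost without WT P18 replicate 2 (0.14), KO P18 replicate 2 (0.12), KO P12 replicate 1 (0.11) or WT P12 replicate 1 (0.10), and the red blood cell call without KO P18 replicate 2 (-0.54) or WT P12 replicate 1 (-0.32). Leaving out KO P12 replicate 1 lost peritubular genes (-0.15), X-linked housekeeping genes (-0.17), endothelium (-0.29) and piRNA (0.39). Leaving out WT P12 replicate 1 lost peritubular genes (-0.08) and endothelium (-0.40), WT P12 replicate 2 lost spermatogonia (-0.09) and piRNA (0.37), and KO P12 replicate 2 lost spermatogonia (-0.09). The recombination list passed in all 8 of these fits, at 0.26 to 1.0, but was at -0.01 (adjusted p = 0.816) without both doubted P18 libraries.

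The first pattern weighed is the Alkbh5 level at P18, which as a percentage of the mean of WT P12 was 0.403% and 0.156% in KO P12, 0.0705% and 64.8% in the libraries labelled WT P18, and 128% and 1.11% in those labelled KO P18. Genotypes as labelled are argued against by the 128% in KO P18 replicate 1, where both KO P12 libraries are under 1%. A mixture of WT and KO RNA that would put a library between 5% and 50% is argued against too, since 0 libraries lay there. The test cannot decide on a mixture mostly of WT RNA, because the WT P12 libraries themselves were at 72.8% and 127%. Nor can it decide on one mostly of KO RNA that stays under 5%. An exchange of labels between libraries at P18 stays open and cannot be told apart from other errors, because its test, 2 libraries out of place with 1 in each genotype, only restates the values that raised it. Across all tested genes the P18 libraries also paired across labels, at r = 0.985 for those without the Alkbh5 transcript and 0.968 for those with it. Within labels r was 0.836 in WT and 0.755 in KO. Other errors that part the libraries as Alkbh5 does would give the same pairs. An exchange does not account for the hepatocyte transcripts, which go with the labels as they stand, and an error involving a sample from outside this series was not tested.

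The second pattern is that late-prophase genes stayed near the WT P12 level in 2 of the 4 P18 libraries: the pachytene and diplotene list was at 0.187 in WT P18 replicate 1 and 0.184 in KO P18 replicate 2, against 2.954 and 3.493 in the other P18 libraries and -0.445 to 0.102 at P12. Younger testes under the P18 label are argued against by the Leydig list minus the Sertoli list, which was at 0.623 in the lower of the 2 libraries, at most 0.035 at P12 and 0.494 in the lower of the other P18 libraries. Liver RNA in the library is argued against by WT P18 replicate 1, where late-prophase genes are as low with a hepatocyte median of 0.068. Loss of Alkbh5 is a candidate explanation, since the 2 libraries with low late-prophase genes are the P18 libraries without the Alkbh5 transcript, and at P12 the list was lower in KO (-0.445 and -0.336) than in WT (-0.11 and 0.102). At P18 it cannot be told apart from chance by design, because 4 libraries divide into pairs in only 3 ways, so no division can have a share under 0.333.

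The third pattern is the hepatocyte transcripts in both libraries labelled KO P18. Of 38 hepatocyte genes tested, 37 were higher in both of these libraries than in each of the 6 others, Ass1 being the exception, so liver RNA in the 2 libraries is a candidate explanation. For many of the 37, such as Alb, Apoa1, Gc and Ttr, the other 6 libraries were under 1 FPKM. Those genes passed the filter only through these 2 libraries, which fixed their order. Loss of Alkbh5 in the testis is argued against, as the lowest hepatocyte median among the 4 libraries without the Alkbh5 transcript was 0 and only 1 of these 4 had a median over 1. KO P18 replicate 1, which has the transcript, was at 2.492. How liver RNA entered, at dissection, extraction or library preparation, was not tested.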

How the results depend on the processing

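The fits without the 2 doubted P18 libraries, with crossed pairs, with DESeq2, with limma as an alternative, and of the 4 P12 libraries alone with those tools, were chosen only after the results were seen, and the others were planned. Alternatives that need FPKM (pseudocount, transcripts scaled to a fixed total, median ratio, quantile, no trend, weights) were run within limma, and the rest within edgeR. Of 7625 alternatives to 329 single-gene results, 7264 were the same, 0 weaker, 344 stronger and 17 reversed. As edgeR called 0 of these genes on all 8 libraries, a weaker result could not occur, and the same means only that the gene was not called either: 118 of the 7264 had the other sign. All 17 reversals came from the fit without the 2 doubted P18 libraries. Some of the genes were named because that fit, or the fit of the P12 libraries alone, called them, so their calls there were fixed by that choice. Alkbh5 at P18 (1.19), counted apart, was at -4.98 without KO P18 replicate 1 and 10.12 without WT P18 replicate 2, uncalled in both. Of 1920 alternatives to 120 gene-list results 1599 were the same, 176 weaker, 76 stronger and 69 reversed. Where a result changed, the cause was not tested, except that leaving libraries out leaves fewer of them. A library alone in its group is assumed to vary like the other groups. A fold threshold and leaving out any 1 library each left 0 genes called. The replicate number as a term left 0 genes called in all 5 comparisons and changed 1 list call, that of pachytene genes at P18 (0.775, adjusted p = 0.0762). The labels give the replicate numbers no meaning. The deviations of same-numbered libraries from their own group mean correlated across genotypes at -0.0489 at P12 and -0.939 at P18. At P18 this is the split of the libraries with the Alkbh5 transcript from those without it, seen across the 16702 tested genes and not in Alkbh5 alone. With P18 libraries paired across numbers, a pairing picked from that split and so absorbing it, 52, 52, 872, 2586 and 72 genes were called (P12, P18, WT with age, KO with age, interaction).

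In the P12 libraries alone 9 genes were called and Alkbh5 was at -8.37, and DESeq2 there called 659 with Alkbh5 at -8.38. DESeq2 on all libraries called 11, 76, 408, 2381 and 45 genes, 1 of them at both ages, with Alkbh5 at 8.18 in KO with age. In the P12 simulation of all 8 libraries, 60.7% of the DESeq2 calls were false. It used the spread shared with the P18 groups (common dispersion 0.226, against 0.0179 for the P12 libraries alone). DESeq2 was simulated for P12 only. The share of false calls among the real DESeq2 calls is therefore not known. Limma as designed called 27 at P18, 31 in KO with age and 7 in the interaction, with 4 lists at P18. In camera on these values retrogenes at P12 (-0.30, adjusted p = 0.134) and Y-linked genes in KO with age (-0.61, adjusted p = 0.0791) were not called. Nor, in the interaction, were endothelium, m6A, spermatogonia and X-linked housekeeping genes (adjusted p = 0.0547 to 0.0625). The pseudocount of 0.1 gave 2 genes at P18, 4 in KO with age and 4 lists at P18, transcripts scaled to a fixed total 11, 17 and 5 lists, and quantile normalization 23, 23 and 3 lists, with 4 genes in the interaction. Median ratio scaling gave 34, 38 and 7 genes, no trend 54, 59 and 20, and array weights 3 and 13. In edgeR, no filter and a filter at 5 FPKM each gave 5 genes in KO with age. With an estimated correlation 0 lists passed in all 5 comparisons, and X-linked genes, in the same order, were at 0.11 (adjusted p = 0.731), -0.093 (0.633), -0.22 (0.519), -0.39 (0.421) and -0.19 (0.602).

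Without the 2 doubted P18 libraries 1, 6357, 7507, 1806 and 2304 genes were called, 1 at both ages, and the KO effects at P12 and P18 correlated at r = 0.460. Alkbh5 was at -8.35 at P12 and -5.98 at P18, a direction fixed by the choice of libraries. At P18, against the direction by label, were Mybl1 -0.72, Odf2 -1.86, Cst8 1.07, Toporsl -6.93, Dmrtb1 -2.18, Pgk2 -6.16, Adam18 -7.17, Fndc3a -0.52, Cmtm2b -7.615, Abca14 -7.09, Uba1y 0.37, Actl7b -6.72 and Gldnos -7.49. For Ms4a19, Speer1 and Ldhal6b, at 0 counts in KO P18 replicate 2, the fitted -11.25, -13.36 and -16.01 depend on the prior count and are no measure of a fold. A floor of 3 counts gives at least 108-fold, 464-fold and 2900-fold. Zpbp2 was at -3.42 in the interaction. Lists passing numbered 13 at P18 and 7 in KO with age. List medians at P18 were retrogenes -1.52, endothelium 0.41, G2 and M phase -0.245, Leydig 0.75, macrophages 0.335, recombination -0.44, pachytene -3.11, peritubular 0.13, piRNA -1.30, Sertoli 0.60, spermatids -2.87, spermatogonia 0.45, synaptonemal complex -0.55, X-linked housekeeping 0.57, Y-linked 0.465 and all X-linked 0.54. Leydig genes were at -0.012 in WT with age. In the interaction the medians were retrogenes -1.21, endothelium 0.25, G2 and M phase -0.029, Leydig 0.565, pachytene -1.89, peritubular 0.10, piRNA -0.98, regulators -0.27, Sertoli 0.39, spermatids -2.48, spermatogonia 0.33, synaptonemal complex -0.039, X-linked housekeeping 0.47, Y-linked 0.41 and all X-linked 0.43.

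Leaving out 1 library at a time, which turned many lists into calls of either sign, gave 5 (without KO P12 replicate 1) to 12 lists at P12, 8 to 17 (without WT P18 replicate 2) at P18, 6 (without WT P18 replicate 2) to 14 in WT with age, 6 (without KO P18 replicate 1) to 15 in KO with age, and 6 (without WT P18 replicate 1) to 17 (without WT P18 replicate 2) in the interaction. At P12 macrophages ranged from -0.41 to 0.37, red blood cells from -0.38 to 0.42 and all X-linked genes from 0.088 to 0.13. At P18 the ranges were retrogenes -0.98 to 0.95, endothelium -0.54 to 0.18, G2 and M phase -0.055 to 0.56, immediate-early -0.38 to 0.53, Leydig -0.63 to 0.37, macrophages -0.65 to 0.094, recombination -0.19 to 0.51, pachytene -2.27 to 2.94, peritubular -0.61 to 0.038, piRNA -0.75 to 1.22, Sertoli -0.66 to 0.24, spermatids -2.07 to 2.63, spermatogonia -0.50 to 0.23, synaptonemal complex -0.26 to 0.62, X-linked housekeeping -0.51 to 0.27 and all X-linked -0.51 to 0.22. In WT with age they were piRNA -0.047 to 1.40, Sertoli -0.47 to 0.14, X-linked housekeeping -0.48 to 0.034 and all X-linked -0.51 to 0.021. In the interaction they were retrogenes -0.67 to 1.89, immediate-early -0.54 to 0.42, pachytene -1.05 to 3.99, peritubular -0.52 to -0.021, piRNA -0.43 to 1.49, Sertoli -0.89 to 0.031, spermatids -1.68 to 2.45, spermatogonia -0.68 to 0.14, X-linked housekeeping -0.62 to 0.16 and all X-linked -0.61 to 0.13. The r of the KO effects at P12 and P18 ranged from -0.440 (without WT P18 replicate 2) to 0.40 (without WT P18 replicate 1).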

Other observations

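The list of 40 hepatocyte genes and every test of it were chosen only after albumin had been seen among the lowest p-values at P18.

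Hepatocyte genes were higher in both libraries labelled KO P18, where the Alkbh5 level goes against the label of replicate 1. Among them were Alb (119 and 111 FPKM, at most 0.612 in the other 6 libraries), Apoa1 (25.8 and 25.5, at most 0.224) and Serpina1c (20.4 and 18.9, at most 0.0586), which has near-identical copies. Trf (23.8 and 38.1) had up to 21.9 FPKM elsewhere and is also in the Sertoli list. Of the 38 genes tested, 7 had a mean of at least 1 FPKM in WT P12. Genes under 1 FPKM in the other 6 libraries passed the filter only through those labelled KO P18. Their direction at P18 and in KO with age was so fixed. The list median at P18 was 6.24 (38 of 38 higher, adjusted p = 1.57e-200 in camera, and 1.16e-05 with an estimated correlation), and in KO with age it was 6.62 (adjusted p = 4.41e-44, and 0.000869 with an estimated correlation). EdgeR called 0 of its genes over all genes, and 37 in each of these comparisons when adjusted over the list alone. For the interaction 19 were called over the list alone. The list was also higher at P12 (0.32, adjusted p = 0.000133, and 0.0575 with an estimated correlation; 1 gene lower over the list alone), where the median was 0 without KO P12 replicate 1 and the call was lost without the 2 doubted P18 libraries (0.315, adjusted p = 0.134) and in limma (0.028, adjusted p = 0.288). It was higher too in WT with age (0.34, adjusted p = 0.000865, and 0.0958 with an estimated correlation; 1 gene higher over the list alone), a call lost without WT P18 replicate 1 (median 0, adjusted p = 0.187). Members without a count in a group numbered 12 at P12, 8 at P18, 12 in WT with age and 3 in KO with age, and setting them at their bounds left the medians where they were.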
